A study of Mus musculus with 9 samples.

How the data were processed

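Mouse embryonic stem (ES) cells of the E14 parental line were profiled by RNA sequencing in 9 libraries, 3 in each of 3 groups. Cells with loxP-flanked (floxed) Zbtb11 alleles and an ERt2-Cre recombinase gene at the Rosa26 locus were kept for 72 h either with the carrier ethanol (ethanol control) or with 250 nM 4-hydroxytamoxifen (4OHT), the ligand that activates ERt2-Cre (the group labelled Zbtb11 KO). Cells with unmodified Zbtb11 and Rosa26 loci were kept with 4OHT for the same time (4OHT control). Groups and replicate numbers were taken from the sample titles and characteristics. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. Per the labels' protocols, ribosomal RNA was removed from 1 μg of total RNA with a depletion kit and directional libraries were made.

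The deposited files hold raw read counts per gene, 1 file per library, under versioned Ensembl gene identifiers, with the 5 closing rows of HTSeq that name no gene. The submitters' processing notes list cutadapt, STAR, HTSeq and edgeR and the build mm9, together with Bowtie 1.1.2, MACS2 and DiffBind, without stating the role of each. The strand setting of the counting is not given in the sources used here, so reads of a gene and an antisense partner may not have been told apart, and genes with near-identical copies are reported as uncertain. Each file had 37310 gene rows, of which 32620 matched a symbol in the GENCODE M21 annotation. That annotation is built on another assembly than the files, so it served for names and transcript sequence only and no coordinates are given. Genes without a symbol held 3.92% of the gene counts. The 5 rows that name no gene stayed out of library totals and tests. Reads that HTSeq assigned to no feature made up 26.4% to 33.8% of the reads in a file, and reads assigned to no single gene 0.78% to 0.91%. Whether the reads without a feature lay between genes, in introns or on the other strand was not examined. The other closing rows were 0.

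Gene counts per library summed to between 16909139 and 23544893. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust glmQLFit) on the deposited counts, with TMM scaling, the filterByExpr filter by group and 1 fit of all 9 libraries with a mean per group, which leaves 6 residual degrees of freedom. It covered 16224 genes. A gene was called at a Benjamini-Hochberg adjusted p (FDR) under 0.05, and "rose", "fell" and "changed" refer to such calls. CPM are edgeR's library-size-scaled counts after TMM scaling, given as mean ± SD over 3 libraries, and log2 fold changes are given with standard errors (SE) where they carry a statement. The 3 comparisons were the labelled KO libraries against the ethanol control, the labelled KO libraries against the 4OHT control, and the 4OHT control against the ethanol control. Overlaps between comparisons that share libraries were set beside 20 simulated sets of unchanged groups and beside the overlap of independent gene lists of the same sizes.

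Before the data were examined, 37 gene lists were written from general knowledge of pathways, complexes and cell types; 1114 of their 1160 members matched an identifier, and 36 lists had at least 5 tested members. Each list was tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 36 lists), again with a correlation estimated for each list, and with fry. Also fixed then were the tests, the alternatives and the rule for naming genes: Zbtb11 and 2 genes at the Rosa26 locus; the 8 largest rises and 8 largest falls against the ethanol control among genes with an official symbol, a mean log2 CPM of at least 2 and the same direction against both controls; up to 4 members with the smallest p from each list past its test and up to 2 from the others; the 6 largest rises and 6 largest falls in the 4OHT control under the same limits of symbol and level; and 16 regulators of pluripotency, p53, stress and mitochondrial pathways. Genes named outside this rule are said to have been chosen after their values were seen.

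Replicate numbers are shared by the 3 groups. In a check of pairing, the deviations of libraries from their group means were correlated across genes. All 9 pairs of libraries with the same number had a positive correlation, from 0.11 to 0.31, so the numbers pair the libraries. Every pair with different numbers had a negative correlation. Deviations cancel within a group, so the negative values follow in part from the positive ones and are not separate evidence. The labels do not say what the pairing stands for. The fit with the replicate number as a block was an alternative fixed beforehand. Its values are given for named genes and lists whose call it changed and for main counts that it moved more than 1.5-fold. Other values with the block, such as counts of list members, are not given.

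The fit was tested on simulated counts with the means and library sizes of the 16224 genes. The 200 genes given a change were drawn only from genes with a mean count of at least 50 per library. The pairing of replicate numbers was not simulated. The shares recovered therefore do not cover genes of few counts. Against the ethanol control it recovered 32% of 50 genes changed 1.25-fold, 86% of 50 changed 1.5-fold, 96% of 50 changed 2-fold and 100% of 50 changed 4-fold, with 14 false calls beside 157 true ones. Against the 4OHT control the shares were 28%, 82%, 94% and 100%, with 9 false calls. Alternatives were RLE size factors, library totals without a composition factor, TMM without mitochondrial genes and the 10 genes with most counts, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, a test against a fold of 1.5 (glmTreat), FDR 0.01, fits of only the groups compared, the replicate block, and leaving out each library.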

Results

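RNA sequencing of mouse ES cells, stem cells derived from the early embryo, was compared between 3 ethanol control libraries, 3 libraries labelled Zbtb11 KO and 3 4OHT control libraries, each collected after 72 h. The comparison of the labelled KO libraries with the ethanol control addresses which transcripts differ once deletion of the floxed Zbtb11 alleles has been induced. The 4OHT control differs from the ethanol control in line as well as drug, so their comparison does not separate an effect of 4OHT from one of the line. Zbtb11 encodes a zinc finger protein of the BTB family of nuclear regulators. Gene counts per library averaged 2.08e+07 ± 3.48e+06 in the ethanol control, 2.04e+07 ± 1.77e+06 in the labelled KO libraries and 2.01e+07 ± 2.29e+06 in the 4OHT control (SD, n = 3). The first principal component of log2 CPM held 48.7% of the variance and set the labelled KO libraries (35.83 to 41.17) apart from both controls. It also set the 4OHT control (-37.85 to -27.81) apart from the ethanol control (-7.57 to -2.49). The second component held 19.4% and set the ethanol control apart from the other groups.

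Transcripts of the targeted gene were measured first. Zbtb11 (ENSMUSG00000022601.9) had 355 ± 6.70 CPM in the ethanol control, 377 ± 8.47 CPM in the labelled KO libraries and 368 ± 9.31 CPM in the 4OHT control (SD, n = 3). Its log2 fold change in the labelled KO libraries against the ethanol control was 0.09 (SE 0.05; edgeR adjusted p = 0.17, or 0.032 with the replicate block and 0.013 with library totals, where it was 0.16). The gene-level count was therefore not lower in the libraries labelled KO. The sources used here do not say which exons the loxP sites flank, and reads from the rest of a transcript would still be counted, so this value checks neither the labels nor the loss of the protein, and the group is called labelled KO throughout. The level of Thumpd3, a gene beside the Rosa26 locus, was 119 ± 5.25 CPM in the ethanol control and 116 ± 7.16 CPM in the labelled KO libraries, against 71.0 ± 4.05 CPM in the 4OHT control. The Rosa26 transcript itself, Gt(ROSA)26Sor, had 2.80 ± 0.53, 5.19 ± 0.35 and 2.63 ± 0.53 CPM in the same order, and rose in the labelled KO libraries against the ethanol control (log2 fold change 0.88, adjusted p = 0.0018).

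**Figure D1:**
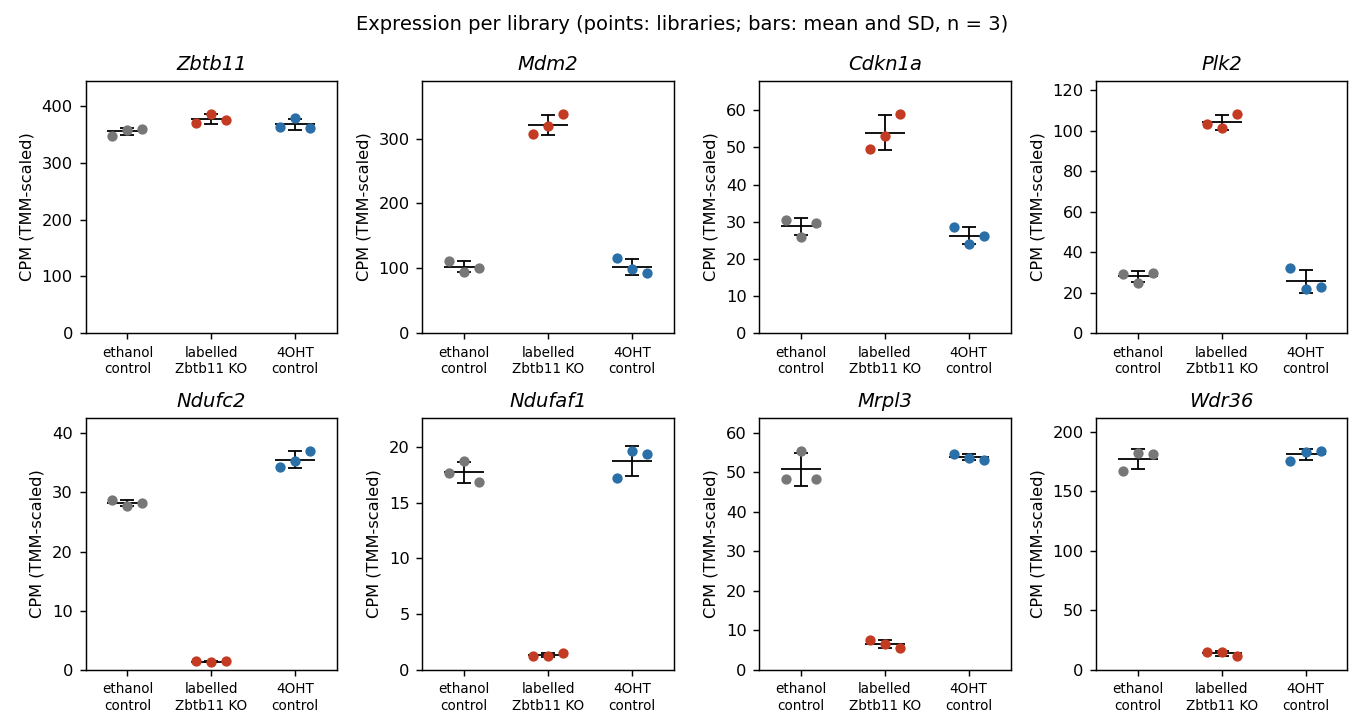
CPM of 8 genes in each of the 9 libraries, by group; points are libraries, horizontal marks are group means and error bars are SD (n = 3), on axes that start at 0. Zbtb11 lies between 348 and 386 CPM in every library, Mdm2, Cdkn1a and Plk2 are higher in the labelled KO libraries, and Ndufc2, Ndufaf1, Mrpl3 and Wdr36 are lower there.

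Against the ethanol control, 35 of 40 p53 target genes rose in the labelled KO libraries, and 25 of 48 proteins of the large and 15 of 33 of the small mitochondrial ribosomal subunit, 29 of 43 S phase genes and 13 of 24 cholesterol synthesis genes fell. These lists passed camera with its preset correlation and not with an estimated correlation (adjusted p = 0.079 for p53 targets, 0.52 for the large subunit and 0.58 for each of the others). Some single genes fell steeply. Ndufc2, a complex I subunit (ENSMUSG00000030647.8), had 28.2 ± 0.52 CPM in the ethanol control and 1.37 ± 0.05 CPM in the labelled KO libraries (log2 fold change -4.36, SE 0.10, adjusted p = 3.3e-14). Other large falls among genes chosen by the fixed rule were Trdmt1, which encodes a tRNA methyltransferase (log2 fold change -4.91), Aar2, a factor of spliceosome assembly (-4.26), Acsf3, a mitochondrial acyl-CoA synthetase (-4.25), Ankrd40 (-4.05), Stx18, a membrane fusion protein of the endoplasmic reticulum (-4.00), Zfp11 (-4.00) and Slc35a3, a Golgi nucleotide-sugar transporter (-3.92). Among genes with a mean log2 CPM of at least 2 and the same direction against both controls, the largest rises were in Prrg2 (2.66), Mdga1 (2.12), Inka2 (2.04), Zfp750 (2.03), Cd80 (1.97), Plk2 (1.90), Dffb, a subunit of the nuclease that cuts DNA in apoptosis (1.86), and Ahnak2 (1.75). Against the 4OHT control, where the rule for naming them already required the same direction, the 16 genes had log2 fold changes from -5.29 for Trdmt1 to 3.26 for Prrg2.

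By edgeR at FDR 0.05, 4417 of 16224 genes changed, 2110 upward and 2307 downward, and 6936 changed with the replicate block. At least 2-fold rises numbered 459 and falls 188, while at least 4-fold rises numbered 40 and falls 73. With library totals as the only scaling the split moved to 3038 rises and 1527 falls, which is 66.6% rises against 47.8%. Of the 71 genes that fell at least 4-fold against both controls, 61 had a mean log2 CPM of at least 2, as did 3 of the 22 that rose at least 4-fold against both.

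The p53 pathway gave the most uniform group. Of 40 tested p53 targets, 35 rose and the other 5 were not called (36 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 2.2e-36, adjusted p = 0.079 with an estimated correlation). Mdm2, the ubiquitin ligase that limits p53, went from 102 ± 8.47 to 321 ± 15.9 CPM (log2 fold change 1.65, SE 0.08, adjusted p = 1.6e-09). Phlda3 (1.42), Ephx1 (1.37) and Eda2r (0.94) had the other smallest p-values in the list, and Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 0.91. Transcripts of p53 itself were at 637 ± 20.6 and 620 ± 46.5 CPM (Trp53, log2 fold change -0.04, adjusted p = 0.67; 0.03 with library totals). In the list of apoptosis genes, 4 of 27 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.30), and Pmaip1 (1.14) and Apaf1 (0.64) were among the rises.

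Of 48 tested proteins of the large subunit of the mitochondrial ribosome 25 fell and 23 were not called (31 fell adjusted over the list alone), with a median log2 fold change of -0.22 (camera adjusted p = 1.7e-21, adjusted p = 0.52 with an estimated correlation). The members with the smallest p were Mrpl1 (-2.68), Mrpl3 (-2.95), Mrpl13 (-2.03) and Mrpl48 (-3.03). Mrpl3 went from 50.8 ± 4.13 to 6.52 ± 0.93 CPM. Mrpl48 has a pseudogene, so its reads may not all be its own. Of 33 small subunit proteins 15 fell and 1 rose (18 and 1 adjusted over the list alone; median -0.17, camera adjusted p = 5.5e-05, adjusted p = 0.58 with an estimated correlation), led by Mrps31 (-2.65), Mrps18c (-1.14), Mrps24 (-0.71) and Mrps27 (-0.64).

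Complex I, the first enzyme of the respiratory chain, showed a few large falls within a list whose median stayed near 0. Of 36 nuclear-encoded subunits 14 fell and 4 rose (14 and 5 adjusted over the list alone), with a median log2 fold change of -0.03 (0.04 with library totals) and a mean of -0.25 (camera adjusted p = 0.00087, adjusted p = 0.58 with an estimated correlation). Besides Ndufc2, these were Ndufs7 (-1.86), Ndufa12 (-1.10) and Ndufa2 (-0.68). Of 17 assembly factors 2 fell (2 adjusted over the list alone): Ndufaf1 (ENSMUSG00000027305.3), from 17.7 ± 0.93 to 1.33 ± 0.15 CPM (log2 fold change -3.74, SE 0.13, adjusted p = 3.5e-12), and Tmem70 (-0.79). Ndufaf7 (-0.27, adjusted p = 0.064) and Tmem186 (0.23, adjusted p = 0.069) were not called in the fit without the block and were called with it (adjusted p = 0.018 and 0.0046). Ndufaf7 was also called without ethanol control replicate 1 (0.018) or KO replicate 3 (0.047), and Tmem186 with library totals (0.018). The assembly list had a median of -0.06 (0.02 with library totals) and a camera adjusted p of 0.031, which became 0.068 with the replicate block, 0.057 with the filter at 1 CPM, 0.14 with DESeq2, 0.054 without KO replicate 1, 0.053 without KO replicate 3 and 0.58 with an estimated correlation. Of 42 subunits of complexes II to V 7 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.63), among them Cyc1 (-0.33) and Atp5a1 (-0.22).

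RNAs encoded in the mitochondrial genome moved in different directions. The 16S ribosomal RNA, mt-Rnr2, fell from 47120 ± 4826 to 22850 ± 2473 CPM (log2 fold change -1.04, SE 0.09, adjusted p = 1.4e-05). The 12S ribosomal RNA, mt-Rnr1, had 22590 ± 4571 and 26860 ± 6391 CPM (0.25, adjusted p = 0.40), with a log2 fold change of 0.03 without KO replicate 3, 0.42 without ethanol control replicate 2 and 0.15 without ethanol control replicate 3. Of 7 tested mRNAs 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 0.0021, adjusted p = 0.58 with an estimated correlation). Rises included mt-Nd2 (0.74), mt-Nd1 (0.62) and mt-Cytb (0.48), and mt-Co1 fell by 0.27. The depletion kit removes ribosomal RNA before sequencing, so levels of mt-Rnr1 and mt-Rnr2 also carry what escaped it. Genes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l had 0 to 2 counts in each library and could not be compared.

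**Figure D2:**
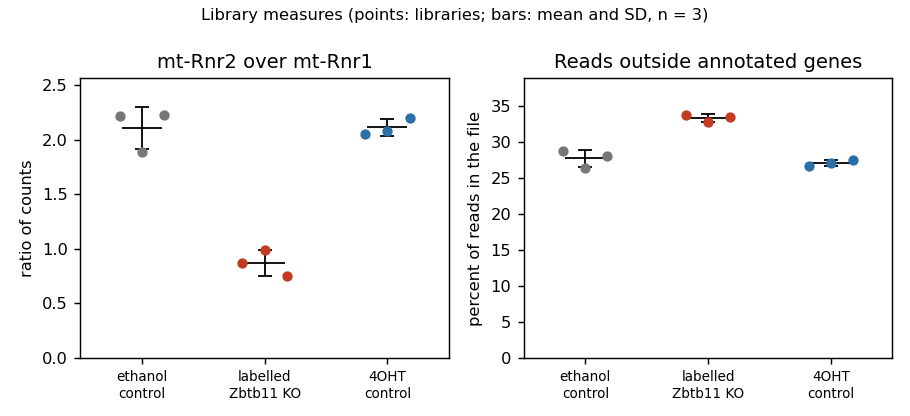
Ratio of mt-Rnr2 to mt-Rnr1 counts (left) and percent of the reads in a file that HTSeq assigned to no feature (right, titled reads outside annotated genes) in each library, by group. Points are libraries, horizontal marks are means and bars are SD (n = 3), on axes that start at 0. The ratio is 0.75 to 0.99 in the labelled KO libraries and 1.89 to 2.23 in the 6 control libraries, and the percent without a feature is 32.7 to 33.8 against 26.4 to 28.7.

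Of 17 mitochondrial aminoacyl-tRNA synthetases 4 fell (4 adjusted over the list alone; camera adjusted p = 0.052), including Tars2 (-1.09) and Rars2 (-0.44). The list had a median of -0.13, a mean of 0.02 and a downward test, with a camera adjusted p of 0.58 with an estimated correlation. With the preset correlation its adjusted p was 0.044 without ethanol control replicate 2, 0.025 without KO replicate 2, and 0.046, 0.044 and 0.047 without 4OHT control replicate 1, 2 and 3. Of 29 genes of mitochondrial DNA maintenance and expression 8 fell and 4 rose (9 and 5 adjusted over the list alone; adjusted p = 0.11), with Tefm (-1.26) and Ssbp1 (-0.95) leading. Of 25 genes of mitochondrial protein import 7 fell (7 adjusted over the list alone; adjusted p = 0.11), such as Timm9 (-0.48) and Timm50 (-0.30). Of 20 mitochondrial chaperones and proteases 4 fell (4 adjusted over the list alone; adjusted p = 0.13), such as Grpel2 (-0.51) and Lonp1 (-0.22). Without KO replicate 2 these last 3 lists passed, with adjusted p = 0.039, 0.0097 and 0.025. With an estimated correlation in the main fit their camera adjusted p was 0.60, 0.69 and 0.69. Among 3 regulators of mitochondrial genes, Gabpa had a log2 fold change of -0.16 (adjusted p = 0.033), Nrf1 of -0.09 (adjusted p = 0.18) and Ppargc1b of -0.31 (adjusted p = 0.12, or 0.019 with the replicate block and 0.019 without KO replicate 3). The call of Gabpa ended with library totals (-0.09, adjusted p = 0.20) and without a filter on low counts (0.054), without ethanol control replicate 1 (0.066) or 2 (0.14) and without KO replicate 1 (0.099). Against the 4OHT control Gabpa fell by 0.22 (adjusted p = 0.0032) and Ppargc1b by 0.39 (adjusted p = 0.040), and Nrf1 was not called (-0.11, adjusted p = 0.085, or 0.023 with the replicate block). That call of Ppargc1b ended with library totals (0.091), in the fit of the groups compared (0.064), without ethanol control replicate 2 (0.054), without KO replicate 1 (0.15) or 2 (0.13) and without 4OHT control replicate 2 (0.11) or 3 (0.14).

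Lists of DNA replication, cholesterol synthesis, glycolysis and the integrated stress response also passed the test downward. Of 43 S phase genes 29 fell and 14 were not called (32 fell adjusted over the list alone; median -0.23, camera adjusted p = 5.5e-07, adjusted p = 0.58 with an estimated correlation), among them Pola1, a DNA polymerase subunit (-0.36), Uhrf1 (-0.42), Ung (-0.41) and Nasp (-0.37). Of 24 cholesterol synthesis genes 13 fell (14 adjusted over the list alone; median -0.29, adjusted p = 0.0013, adjusted p = 0.58 with an estimated correlation), including Cyp51 (-0.55), Sqle (-0.35), Msmo1 (-0.40) and the regulator Srebf2 (-0.44). Of 23 glycolysis genes 8 fell (8 adjusted over the list alone; median -0.29, adjusted p = 0.00088, adjusted p = 0.60 with an estimated correlation), including Pdk1 (-0.74), Hk2 (-0.68), Pfkp (-0.88) and Slc16a1 (-0.29). In the related list of 24 hypoxia genes 4 fell and 2 rose (4 and 2 adjusted over the list alone), with Pdk1 again and Gys1 (-0.44) falling. The hypoxia list had a camera adjusted p of 0.11, or 0.0025 with the replicate block, 0.044 without KO replicate 3 and 0.69 with an estimated correlation. Of 46 targets of the integrated stress response, driven by Atf4 and Ddit3, 24 fell and 6 rose (26 and 6 adjusted over the list alone; median -0.30, adjusted p = 0.00088, adjusted p = 0.60 with an estimated correlation). Against the 4OHT control this list did not pass, with 12 falls and 8 rises (13 and 8 adjusted over the list alone; median -0.08, or 0.01 with library totals, adjusted p = 0.67). Wars (-0.60), Slc7a3 (-0.73) and Mars (-0.34) fell and Sesn2, which p53 also controls, rose by 0.49. Atf4 had a log2 fold change of -0.10 (adjusted p = 0.25) and Ddit3 of 0.38 (adjusted p = 0.048). The call of Ddit3 ended with DESeq2 (0.095) and RLE factors (0.053), without ethanol control replicate 1 (0.15), 2 (0.091) or 3 (0.083), without KO replicate 1 (0.26) or 3 (0.10) and without 4OHT control replicate 2 (0.056).

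Of 76 cytosolic ribosomal proteins 32 rose and 1 fell (38 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.00015, adjusted p = 0.60 with an estimated correlation), for example Rps19 (0.31), Rps26 (0.25), Rps7 (0.26) and Rps15a (0.26), which have pseudogenes that may share reads. Of 12 host genes of small nucleolar RNAs 4 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.020, adjusted p = 0.58 with an estimated correlation). Gas5 (0.73), Snhg17 (0.59) and Snhg15 (0.63) rose, and Cct6a, which encodes a chaperonin subunit, fell by 0.43. Of 53 ribosome biogenesis genes 12 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.07, adjusted p = 0.0026, adjusted p = 0.69 with an estimated correlation). Wdr36, a factor of small subunit processing, went from 177 ± 8.65 to 13.9 ± 2.07 CPM (log2 fold change -3.67, SE 0.08), Polr1b (-0.58) and Tcof1 (-0.42) fell and Pwp2 rose by 0.34. Of 25 targets of Nfe2l2, the regulator of the oxidative stress response, 11 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.0021, adjusted p = 0.58 with an estimated correlation). These include Ephx1, which is also in the p53 list, Nqo1 (0.79), Srxn1 (0.53) and Sqstm1 (0.35), whereas Nfe2l2 itself had a log2 fold change of 0.08 (adjusted p = 0.30).

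Of 29 genes of naive and core pluripotency 8 fell and 21 were not called (8 fell adjusted over the list alone; median -0.12, camera adjusted p = 0.058). The list passed with the replicate block (adjusted p = 0.022), in the fit of the groups compared (0.027), without a filter on low counts (0.00065), without ethanol control replicate 2 (0.044) or 3 (0.037), without KO replicate 1 (0.030) or 2 (0.039) and without 4OHT control replicate 1 (0.026), 2 (0.031) or 3 (0.047). With an estimated correlation the list had a camera adjusted p of 0.58 in the main fit. Klf5 and Nr0b1 each fell by 0.45. Nanog (0.05, adjusted p = 0.83) and Sox2 (-0.01, adjusted p = 0.95; 0.06 with library totals) were not called, nor were Pou5f1 (-0.14, adjusted p = 0.064) and Klf4 (0.25, adjusted p = 0.070), which were called with the replicate block (adjusted p = 0.0024 and 1.8e-06) and without KO replicate 2 (0.0050 and 0.014). Pou5f1 was also called with RLE factors (0.050) and DESeq2 (0.041). Klf4 was also called without 4OHT control replicate 1 (0.044) or 2 (0.050). Esrrb (-0.24, adjusted p = 0.031) and Ccnd1 (-0.32, adjusted p = 0.021) fell. The call of Esrrb ended with library totals (adjusted p = 0.14), without ethanol control replicate 1 (0.083) or 3 (0.080) and without KO replicate 1 (0.053) or 2 (0.086). The call of Ccnd1 ended without ethanol control replicate 2 (0.089) or 3 (0.063) and without KO replicate 1 (0.058) or 3 (0.054). Myc was variable (57.6 ± 9.21 against 49.2 ± 16.2 CPM, adjusted p = 0.57, or 0.042 with the block). Of 18 formative and primed genes 3 fell and 1 rose (3 and 1 adjusted over the list alone; adjusted p = 0.32), with Lef1 (-0.79) and Dnmt3b (-0.65) falling.

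In the list of 15 genes of 2-cell-like cells, a rare ES cell state, 8 rose (9 adjusted over the list alone; median 0.85, adjusted p = 0.0027, adjusted p = 0.58 with an estimated correlation). These included Gm8300 (2.60 ± 0.38 to 5.94 ± 0.86 CPM), Usp17le (2.15 ± 0.27 to 4.42 ± 0.84 CPM), Arg2 and Usp17ld, and apart from Arg2 they belong to families of near-identical copies, so their counts are uncertain. Rises numbered 2 of 16 primitive streak and mesoderm genes (2 adjusted over the list alone; adjusted p = 0.11), 4 of 20 endoderm genes with 2 falls (4 and 2; adjusted p = 0.23), 1 of 13 neural genes (1; adjusted p = 0.71), 2 of 17 trophoblast genes (0; adjusted p = 0.47) and 4 of 25 germline genes with 2 falls (4 and 2; adjusted p = 0.55), where the numbers in brackets before the p are adjusted over the list alone. Genes with rises here were Wnt3 (1.82), Snai1 (0.78), Foxa1 (1.58), Gata6 (1.199), Neurod1 (0.56), Gata2 (0.68), Krt7 (0.88) and Sycp2 (0.78), all but Neurod1 and Sycp2 below 4 CPM, and Sohlh2 fell by 0.40. The call of Snai1 ended without ethanol control replicate 1 (adjusted p = 0.073) or KO replicate 1 (0.067), and that of Gata2 without ethanol control replicate 3 (0.063) or KO replicate 1 (0.054) or 2 (0.073). Krt7 lost its call with DESeq2 (0.077), without ethanol control replicate 1 (0.054), 2 (0.098) or 3 (0.069) and without KO replicate 1 (0.17) or 3 (0.052). Irx3 was not called (0.83, adjusted p = 0.068), and was called with library totals (0.050), the replicate block (0.0054) and without ethanol control replicate 3 (0.018) or KO replicate 2 (0.026). In the list of 12 fibroblast genes 1 fell (1 adjusted over the list alone; adjusted p = 0.88), Fn1 (-0.45). Col6a2 was not called (0.63, adjusted p = 0.050), and was with library totals (0.031), the replicate block (0.016) and without KO replicate 2 (0.021) or 4OHT control replicate 1 (0.048) or 2 (0.047). Among 4 tested Hox genes, too few for a list test, Hoxb9 (1.55), Hoxc13 (1.62) and Hoxd13 (1.58) rose from at most 1.02 CPM.

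The remaining lists did not pass. Of 51 genes of G2 and M phase 8 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.45), with Psrc1 (0.64) and Gtse1 (0.55) leading. Of 25 genes of the unfolded protein response 8 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.27), of 38 replication-dependent histones 2 fell (1 adjusted over the list alone; adjusted p = 0.80), of 21 interferon genes 4 fell and 2 rose (4 and 2 adjusted over the list alone; adjusted p = 0.40), of 16 estrogen receptor targets 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.54) and of 36 imprinted genes 7 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.63). Single genes called in these lists included Hsp90b1 (-0.34), Pdia6 (-0.26), Hist1h2af (-0.31), Ddx58 (-0.76), Cxcl10 (1.45), Lif (1.60), Ctsd (0.53), Mkrn3 (-2.92) and Cd81 (0.64). The histone genes Hist1h2af and Hist1h2be have near-identical copies, so their counts are uncertain. The call of Hist1h2be (-0.20, adjusted p = 0.046) ended with library totals (0.17), without ethanol control replicate 2 (0.17) or 3 (0.17), without KO replicate 1 (0.15) or 3 (0.10) and without 4OHT control replicate 2 (0.050). The list median and the list mean or test differed in sign for the neural, fibroblast and estrogen receptor lists. With library totals the medians of the lists of complexes II to V, mitochondrial DNA maintenance, histones and neural genes turned from below to above 0. In all, 15 of 36 lists passed camera with the preset correlation, at which 17 had an unadjusted p under 0.05. With an estimated correlation 0 passed (smallest adjusted p = 0.079, 2 lists with an unadjusted p under 0.05), and fry, which does not compare a list with other genes, passed 22. With DESeq2 the pluripotency (0.0075), mitochondrial import (0.018), chaperone (0.025) and hypoxia (0.025) lists passed as well. Other divisions of the same 6 libraries into 3 and 3 passed up to 18 lists with the preset correlation.

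**Figure D3:**
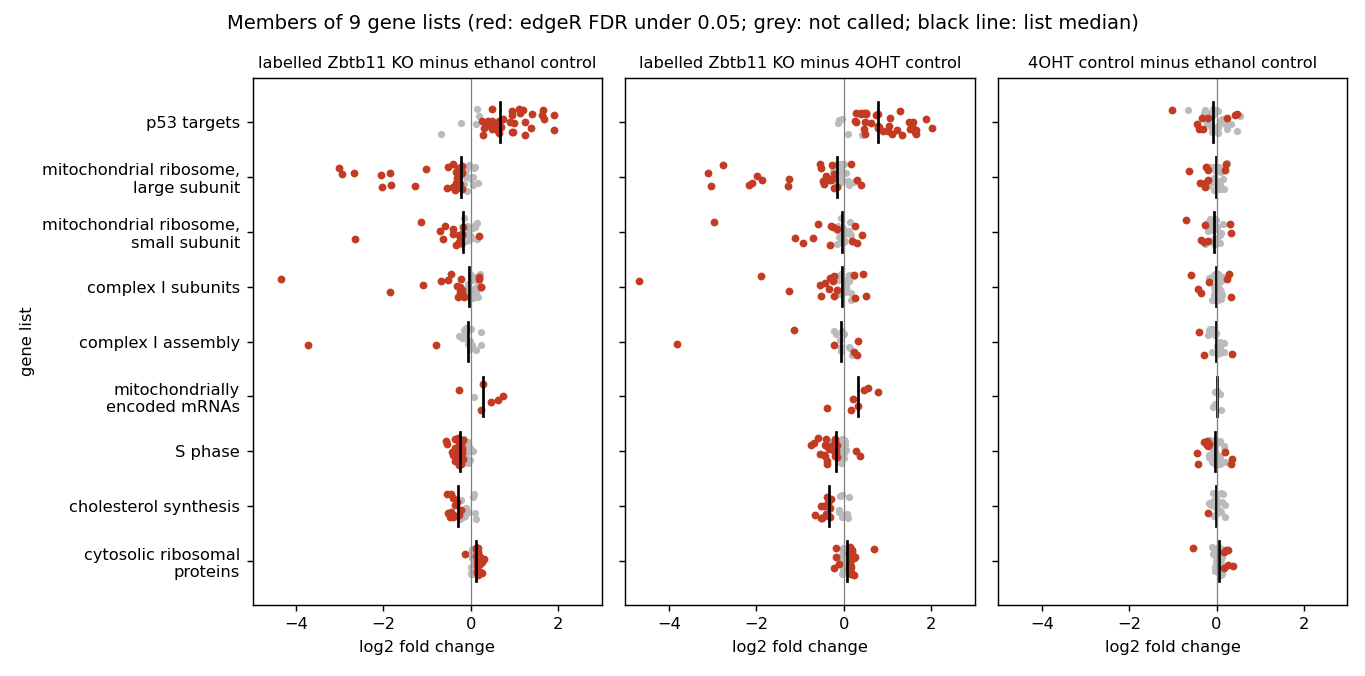
Log2 fold change (x axis) of each tested member of 9 gene lists (y axis) in the 3 comparisons; red points are genes past FDR 0.05 by edgeR, grey points are not called, and black lines are list medians. The p53 targets lie to the right in both comparisons of the labelled KO libraries (medians 0.67 and 0.79) and around 0 in the 4OHT control against the ethanol control (-0.09), and the steep falls of single mitochondrial genes appear in the first 2 panels. With library totals the complex I medians of the first 2 panels turn to 0.04 and the assembly factor medians to 0.02 and 0.03.

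Against the 4OHT control, which shares the drug but not the line, the list of p53 targets again passed upward and that of the large mitochondrial ribosomal subunit downward. Of the 40 p53 targets 34 rose and 6 were not called (34 rose adjusted over the list alone; median 0.79, camera adjusted p = 1.5e-27, adjusted p = 0.13 with an estimated correlation). Of the 48 large subunit proteins 22 fell and 3 rose (26 and 4 adjusted over the list alone; median -0.16, adjusted p = 6.4e-12, adjusted p = 0.66 with an estimated correlation). Ndufc2 fell by 4.69, Ndufaf1 by 3.81, Wdr36 by 3.70 and mt-Rnr2 by 1.18. In all 6319 genes changed, 3103 upward and 3216 downward, with 679 rises and 468 falls of at least 2-fold. Library totals gave 4215 rises and 2328 falls (64.4% rises against 49.1%), with the median log2 fold change of all genes at 0.10 against 0.02.

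The other lists past the test in this comparison were Nfe2l2 targets (14 rose and 2 fell, or 16 and 3 adjusted over the list alone; adjusted p = 0.0012), S phase (23 fell and 2 rose, or 26 and 2 adjusted over the list alone; 0.0062), complex I subunits (12 fell and 4 rose, or 12 and 4 adjusted over the list alone; 0.033), cholesterol synthesis (14 fell, or 14 adjusted over the list alone; 0.033), mitochondrially encoded mRNAs (6 rose and 1 fell, or 6 and 1 adjusted over the list alone; 0.033) and endoderm (10 rose and 1 fell, or 10 and 2 adjusted over the list alone; 0.039), with adjusted p = 0.66 or more for each with an estimated correlation. Endoderm members with the smallest p were Lama1, which encodes a basement membrane laminin (0.78), and Gata6 (1.46), while Lama1 fell by 0.25 against the ethanol control. Single libraries ended some of these calls. Endoderm was lost without KO replicate 1 (0.051) or 4OHT control replicate 2 (0.078) and with library totals (0.055). Complex I was lost without KO replicate 3 (0.058) or 4OHT control replicate 2 (0.053), with library totals (0.069) and with DESeq2 (0.16). Cholesterol synthesis was lost without KO replicate 1 (0.058) or 4OHT control replicate 2 (0.061), and the mitochondrial mRNAs without 4OHT control replicate 1 (0.057). The filter at 1 CPM ended these calls too (0.051 to 0.059). The replicate block added glycolysis (0.00050 against 0.16), formative genes (0.010 against 0.050), pluripotency (0.023 against 0.099) and trophoblast (0.038 against 0.089). Of the 18 formative genes 11 fell and 3 rose (11 and 3 adjusted over the list alone; median -0.52), and of the 29 pluripotency genes 11 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.17). Both lists passed with DESeq2 (0.021 and 0.022) and without a filter on low counts (0.0014 and 0.0027), and the formative list with library totals (0.039) and in the fit of the groups compared (0.031). Formative genes also passed without ethanol control replicate 1 (0.029), 2 (0.046) or 3 (0.026), KO replicate 2 (0.033) or 4OHT control replicate 1 (0.020) or 3 (0.029), glycolysis without KO replicate 3 (0.044), and trophoblast without KO replicate 3 (0.047) or 4OHT control replicate 1 (0.031). With an estimated correlation 0 of 36 lists passed, against 8 with the preset one and 19 by fry (1 and 14 lists had an unadjusted camera p under 0.05), and other divisions of the 6 libraries passed up to 18. List medians and means differed in sign for neural, import, G2 and M phase and apoptosis genes. With library totals several list medians turned from below to above 0, those of complex I (0.04), its assembly factors (0.03), complexes II to V, the small mitochondrial ribosomal subunit (0.05), synthetases, mitochondrial DNA maintenance, import, ribosome biogenesis, G2 and M phase, histones, the integrated stress and unfolded protein responses and apoptosis.

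Of the 15 lists past the test against the ethanol control, 7 passed here and 8 did not, and the difference between the comparisons was not tested. Besides the integrated stress response, those that did not included the small mitochondrial ribosomal subunit (9 fell and 4 rose, or 9 and 4 adjusted over the list alone; median -0.03, adjusted p = 0.088), complex I assembly factors (3 fell and 3 rose, or 3 and 3 adjusted over the list alone; 0.17) and 2-cell-like genes (2 rose and 2 fell, or 2 and 2 adjusted over the list alone; 0.69). Glycolysis (10 fell and 3 rose, or 10 and 3 adjusted over the list alone; 0.16) and cytosolic ribosomal proteins (21 rose and 4 fell, or 20 and 3 adjusted over the list alone; 0.092) did not pass either. The last were ribosome biogenesis (16 fell and 5 rose, or 18 and 5 adjusted over the list alone; 0.099) and host genes of small nucleolar RNAs (5 rose and 1 fell, or 5 and 1 adjusted over the list alone; 0.16). The small subunit list passed without KO replicate 2 (0.015) or 4OHT control replicate 1 (0.031). Ribosome biogenesis passed without KO replicate 2 (0.0085) or 4OHT control replicate 1 (0.036). Ribosomal proteins passed without KO replicate 3 (0.029), with library totals (0.011) and with DESeq2 (0.0070). Glycolysis passed with DESeq2 (0.032), with the replicate block (0.0005) and without KO replicate 3 (0.044). Without a filter on low counts these 4 lists passed as well (0.028 for ribosomal proteins and 0.014 for each of the others).

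Calls against both controls overlapped. In the same direction against both were 2999 genes, 1442 upward and 1557 downward, and 115 were called in opposite directions. Independent lists of these sizes would share 861 genes, and 20 simulations of unchanged groups gave a mean of 0.2 and at most 2. The simulated groups hold no change and no pairing, so their small overlap follows from the setting. It does not show what the shared libraries add when many genes are called. The replicate block gave 4691 genes in the same direction. Both comparisons use the same labelled KO libraries, and 3 libraries cannot be split into parts of 2, so part of the excess may come from the shared libraries.

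The 4OHT control differed from the ethanol control in both line and drug, and the strongest differences mark the line. Genes of the Y chromosome were present in the 4OHT control alone: Ddx3y had 1541 to 2033 counts per library there and 1 count in total in the 6 libraries of the floxed line, Eif2s3y 1082 to 1424 and at most 1 per library, Uty 748 to 887 and at most 2 per library, and Uba1y 438 to 545 and 0. No fold is given for these 4 genes. Trpc5os (log2 fold change 4.80) and the imprinted RNA H19 (3.67, from 0.84 ± 0.12 to 10.8 ± 1.53 CPM) were higher in the 4OHT control, and Acta2, a smooth muscle actin (-3.19), Alg13 (-2.24), Usp26 (-1.99), Srrm4os (-1.87), Zbp1 (-1.81) and Plac8 (-1.58) were lower, all with a mean log2 CPM of at least 2. Below that level and chosen after its values were seen, Esr1, which encodes an estrogen receptor, had 3.52 ± 0.43 CPM in the ethanol control and 0.11 ± 0.09 CPM in the 4OHT control (log2 fold change -5.02, adjusted p = 2.8e-07). The labelled KO libraries, which also received 4OHT, had 3.37 ± 0.23 CPM. Both groups at that level carry ERt2-Cre, and whether its reads count toward Esr1 was not examined. By edgeR 2987 genes changed, 1567 upward and 1420 downward, with 206 rises and 163 falls of at least 2-fold, and 5323 changed with the replicate block. The count was 1974 without ethanol control replicate 2.

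Only 4 lists passed in this comparison. Of 46 integrated stress response targets 14 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.14, camera adjusted p = 0.0078). Lars fell by 0.34, while Slc38a2 rose by 0.27. Atf4 fell by 0.33. Of 15 genes of the 2-cell-like list 4 rose (4 adjusted over the list alone; adjusted p = 0.022), including Pramel6 (1.66) and Usp17le (0.74). Of 25 germline genes 9 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.026), including Mael (0.83) and Stra8 (0.74). Of 25 genes of mitochondrial protein import 5 fell (8 adjusted over the list alone; adjusted p = 0.022), including Tomm34 (-0.68) and Dnajc19 (-0.29). All 4 were lost without 4OHT control replicate 1 (adjusted p from 0.050 to 0.17), the germline and import lists without ethanol control replicate 2 (both 0.063), and all with an estimated correlation (adjusted p = 0.98). Lists with an unadjusted camera p under 0.05 numbered 10 with the preset and 0 with the estimated correlation, fry passed 0, and other divisions of the 6 libraries passed up to 13. The calls of Usp17le and Dnajc19 were lost without ethanol control replicate 2 (0.097 and 0.082) or 4OHT control replicate 1 (0.091 and 0.064). With the replicate block the formative (adjusted p = 0.022), endoderm (0.040), trophoblast (0.022) and fibroblast (0.022) lists passed too. Without ethanol control replicate 3 the formative (0.028), endoderm (0.041), trophoblast (0.041) and histone (0.041) lists passed, without ethanol control replicate 1 the fibroblast list (0.023), and without 4OHT control replicate 3 the formative (0.037) and glycolysis (0.016) lists. Median, mean or test differed in sign for the neural, synthetase, chaperone, complex II to V, estrogen receptor, imprinted and cholesterol lists. Of the 40 p53 targets 3 rose and 6 fell (4 and 7 adjusted over the list alone; median -0.09, adjusted p = 0.41), and Mdm2 had 102 ± 8.47 and 102 ± 12.2 CPM. Klf4 rose by 0.36 and Nfe2l2 fell by 0.24.

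Changes of the labelled KO libraries and of the 4OHT control, each against the ethanol control, had 673 genes in the same direction, 242 upward and 431 downward, and 404 in opposite directions. Independent lists would share 406 and 408, and simulated unchanged groups gave a mean of 0.05 and at most 1. As above, the small simulated overlap follows from groups without change and does not show what the shared libraries add. The replicate block gave 1684 in the same direction. Of 100 divisions of the 9 libraries that keep the pairing of replicate numbers, 9 gave as many. These include the real one and 2 with the real groups and another of them shared. Each of the 9 kept a real group whole as the shared one, so their share is not a rate of chance overlaps. Without ethanol control replicate 2 the overlap held 349 genes, and without replicate 3 it held 419. Part of the excess may come from the shared ethanol control, whose 3 libraries cannot be split.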

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

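The tests of 4OHT, of Cre, of mt-Rnr2 and of splits that keep the pairing were chosen after the results were seen, and the others before.

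In the 3 labelled KO libraries HTSeq assigned 33.29% of the reads to no feature (SD 0.531), against 27.4% in the 6 control libraries. Whether these reads lay between genes, in introns or on the other strand of a gene was not examined. An exact permutation test over 84 regroupings gave two-sided p = 0.0238, the smallest it can give. That test pools controls that differ in line and drug, and it ignores the pairing of replicate numbers. Against each control alone, an exact permutation test over 20 regroupings gave two-sided p = 0.1, again the smallest it can give. The higher share was flagged as a signal in data that the comparisons do not use. Fewer mitochondrial ribosomal reads in the total do not account for it, since the difference was 5.595 percentage points without them. Genomic DNA in the libraries stays open: olfactory and vomeronasal receptor genes had 1.16 times the summed CPM of the controls (1.06 to 1.21 on leaving out a library), between the bounds set beforehand. No biological explanation was tested.

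The p53 targets had a median log2 fold change of 0.67 in the labelled KO libraries, where 35 of 40 rose. An effect of 4OHT as the sole cause is argued against by their median of -0.085 in the 4OHT control, but that control is of another line, and a difference of the lines that hides such an effect was not tested. A trend with GC content or transcript length is argued against by a median of 0.65 after its removal (40 of 40 targets). Cre activity after 4OHT cannot be told apart from the loss of Zbtb11, as 0 libraries of 4OHT-treated ERt2-Cre cells without floxed alleles were analysed here. The loss of Zbtb11, named by the design, stays among the open explanations.

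mt-Rnr2 was lower in the labelled KO libraries (log2 fold change -1.04). Weaker or stronger depletion of all ribosomal RNA alike is argued against by mt-Rnr1 (0.25, SE 0.20), which was not called and was 0.03 (SE 0.14) without KO replicate 3, where mt-Rnr2 was -1.14, and 0.42 and 0.15 without ethanol control replicates 2 and 3. A loss of all mitochondrial transcripts is argued against by the median of the mitochondrial mRNAs (0.29, or 0.19 without ethanol control replicate 3). A difference in depletion acting on mt-Rnr2 alone stays open, as RNA without depletion was not analysed here, and so does the loss of Zbtb11. The ratio of mt-Rnr2 to mt-Rnr1 was 0.868 against 2.11 in both controls. With the controls pooled and the pairing ignored, an exact permutation test over 84 regroupings gave two-sided p = 0.0238, the smallest it can give. Against each control alone, an exact permutation test over 20 regroupings gave two-sided p = 0.1, again the smallest it can give.

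For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. By edgeR in fits of the 6 libraries the real split gave 4404, 5845 and 3024 genes (the labelled KO libraries against the ethanol control, against the 4OHT control, and the 4OHT control against the ethanol control). In each comparison 1 of 10 splits gave as many, the real one, and the highest other gave 0 genes, with at most 827, 487 and 834 genes at an unadjusted p under 0.05. DESeq2 was not run on the other splits. For gene lists the real splits gave 16, 9 and 4 and the highest others 18, 18 and 13, with 2, 9 and 8 of 10 splits giving as many as the real one. Among splits that part 3 pairs of replicate numbers, as the real ones do, the highest others were 13, 10 and 7. Calls of lists with the preset correlation are weak evidence in each of these comparisons.

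For the 2999 genes changed the same way against both controls, 1 of 100 drawn splits of the 9 libraries, the real one, gave as many, and the highest other gave 948. These draws ignore the pairing of replicate numbers. Among 100 of the 108 splits with each number once in every group, 1 gave as many and the highest other gave 2016. The split with 2016 kept the 3 real groups with another of them shared, and splits whose shared group mixed the real groups gave 0 genes. No other drawn split reached 2999 in either set. Splits that mix the real groups put real differences into the spread within groups, so they could hardly reach it. Splits that keep a real group whole are not free of real differences. Neither kind settles whether a random grouping could give this overlap. The splits cannot tell how much of the overlap comes from the shared labelled KO libraries. For the 673 genes changed the same way in the labelled KO libraries and the 4OHT control, 2 of 100 splits that ignore the pairing gave as many (highest other 948), but 9 of 100 that keep it did (highest other 2999), so chance is not excluded for this overlap. These 9 include the real one and 2 with the real groups and another of them shared, and each of the 9 kept a real group whole as the shared one. Splits whose shared group mixed the real groups gave 0 genes. Splits that keep a real group whole are not free of real differences, so they cannot settle chance for this overlap. The split with 948 genes did not keep the 3 real groups whole.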

How the results depend on the processing

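All alternatives below were planned. Without a filter the lists past the test numbered 24, 17 and 7 (labelled KO against ethanol control, labelled KO against 4OHT control, 4OHT control against ethanol control), against 15, 8 and 4, and the filter at 1 CPM gave 4 for the labelled KO libraries against the 4OHT control. A fold of 1.5 (glmTreat) left 372, 887 and 166 genes, 322 in the overlap of both controls and 2 in the overlap on the ethanol control. FDR 0.01 left 2520, 4168 and 1602 genes, overlaps of 1716 and 243, and 4 and 1 lists in the comparisons with the 4OHT control (labelled KO and ethanol control). The replicate block gave 6936 and 5323 genes for the labelled KO libraries and the 4OHT control against the ethanol control, overlaps of 4691 and 1684, and 8 lists for the latter. An estimated correlation gave 0, 0 and 0 lists with camera, with 2, 1 and 0 at an unadjusted p under 0.05 and 22, 19 and 0 by fry. Leaving out single libraries gave 1974 (without ethanol control replicate 2) to 3069 genes for the 4OHT control against the ethanol control, 349 (without ethanol control replicate 2) to 642 genes in the overlap on the ethanol control, which was 419 without ethanol control replicate 3, 5 (without 4OHT control replicate 2) to 11 lists for the labelled KO libraries against the 4OHT control, and 0 (without 4OHT control replicate 1) to 8 lists (without ethanol control replicate 3) for the 4OHT control against the ethanol control, where 2 remained past without ethanol control replicate 2. Zbtb11 passed FDR 0.05 with library totals (log2 fold change 0.16) and with the block (0.0859). Stricter thresholds lower counts by construction, and the cause of the other differences was not tested. The main results are counts of genes or lists and the fold change of Zbtb11. Under all alternatives 138 of their values were within 1.5 times the reported count or, for Zbtb11, on the same side of the threshold, 11 were above that range or newly past the threshold, and 22 were counts below it. Of the values of named genes and lists 5015 kept their side of the threshold, 115 newly passed it and 201 no longer did, with no called value reversing. Medians and folds that were not called and changed sign with the scaling count as unmoved. Depth may limit genes of few counts, which was not tested. Of the 22 genes that rose at least 4-fold against both controls, 3 reach a mean log2 CPM of 2.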

Other observations

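The tests for over-represented mitochondrial genes and for translation factors were chosen after the results were seen, and the 3 sequence motifs before.

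Of the 71 genes that fell at least 4-fold against both controls, 8 belong to the 9 lists of nuclear-encoded mitochondrial genes, which hold 267 of the 16224 tested genes (odds ratio 7.79, Fisher's exact test, two-sided p = 2.1e-05). Fisher's test did not match genes for expression level, and 61 of the 71 genes had a mean log2 CPM of at least 2. It was run on data in which the falls had been seen, so a tie between these falls and mitochondrial function is a hypothesis. Binding sites in the first 100 bases of transcripts were searched in 70 of these genes against 10000 matched lists, for 3 motifs. The motif of GABP (CCGGAAG) was in 11 genes, 15.7% against 9.02% in matched lists (one-sided permutation p = 0.0462, adjusted p = 0.139), so it did not pass. The motif of NRF1 (GCATGCGC) was in 0% (1.51% in matched lists, adjusted p = 1) and that of YY1 (AAGATGGC) in 4.29% (4.27% in matched lists, adjusted p = 0.869). The search covers transcribed sequence only, since promoter sequence was not used here.

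Of 76 cytosolic ribosomal proteins 32 rose and 1 fell in the labelled KO libraries against the ethanol control (38 and 1 adjusted over the list alone), and of 12 host genes of small nucleolar RNAs 4 rose and 1 fell (4 and 1). Both lists passed camera with the preset correlation, but not with an estimated one (adjusted p = 0.60 and 0.58), nor against the 4OHT control with TMM scaling (0.092 and 0.16). A rise of all transcripts with a 5' TOP motif, which ties their translation to growth signals, was tested on 24 translation factors chosen after seeing the data. Their median log2 fold change was 0.00941 (quartiles -0.05 and 0.13) and the camera p was 0.72. Of these genes 5 rose and 2 fell. The quartiles take in the median of the ribosomal proteins (0.12), so the test leaves the question open.

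Gm23935, an RNA gene without a known function, had 12953 CPM before TMM scaling in KO replicate 3, against 4177 to 6124 CPM in the other libraries. KO replicate 3 also had the highest mt-Rnr1 of the labelled KO libraries. It had 34200 CPM after TMM scaling, against 23830 and 22550 CPM in KO replicates 1 and 2. Lars2, a mitochondrial synthetase chosen here after its values were seen, had 437 ± 642 CPM in the labelled KO libraries and 68.3 ± 36.5 CPM in the ethanol control (SD, n = 3) and was not called (edgeR adjusted p = 0.18). An SD this far above the mean of 3 libraries means that the mean rests largely on a single library. The mean is therefore no measure of the group, and the value of each library is not given here. The log2 fold change of Lars2, 2.68 (SE 1.28), was the highest in the synthetase list, whose mean was 0.02 and median -0.13.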
